A study of Arabidopsis thaliana with 32 samples.

How the data were processed

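RNA was measured in endosperm and embryo of Arabidopsis thaliana seeds, 2 tissues separated from each other by laser capture microdissection. Seeds came from the accessions Col and C24 after selfing, from both reciprocal crosses between them, and from crosses of CNS lines, which combine the nucleus of 1 accession with the cytoplasm, and so the chloroplasts and mitochondria, of the other. Each tissue of each cross is a group of 2 libraries, which makes 16 groups and 32 libraries. Per the labels' protocols, RNA was isolated with the RNAqueous Micro Kit and libraries were made with the NEB Ultra II kit after poly-A selection. Trimmomatic, STAR, HTSeq, edgeR and the TAIR10 build are named without roles or versions, per the submitters' processing notes. Whether counting used strand is not given in the sources used here, so reads of a gene and of an antisense neighbour cannot be told apart. Reads shared within families of near-identical genes (SK, LCR, SADHU, PHE1 with PHE2) make the values of single members uncertain.

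The authors deposited 1 table of read counts per gene for each of the 32 libraries, unnormalised, with 33602 genes. Of these, 32835 matched a gene of the symbol table by identifier. The 5 closing summary lines of each table name no gene and stayed out of library sizes and tests; reads without a feature came to 2.28% to 17.7% of all counts with those lines. For the 16 hybrid libraries the authors also deposited read counts per gene for the reference allele (taken as Col) and the other allele (taken as C24). The step that split reads by allele is not given in the sources used here. Total counts per library ran from 8.64 to 54.3 M (median 28.0 M; M is 1e6), and nuclear allele reads from 1.42 to 6.19 M. Depth sets the precision of every value, and intervals and floors given here cover counting error only, since the reads carry no molecular identifiers. Positions are those of the TAIR10 annotation.

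Gene counts were fitted with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood model, after TMM scaling and a filter on low counts (filterByExpr by group, minimum count 10). Adjusted p is Benjamini-Hochberg over the genes tested, and a gene is called when it is under 0.05. Comparisons within a tissue came from a single fit of the 16 libraries of that tissue, in which 8 groups share an estimate of the spread. Tissue comparisons came from a fit of the 16 libraries of the standard crosses and another of the 16 CNS libraries. Levels are TMM-scaled counts per 1e6 (CPM), as mean ± SD over the libraries. Folds against a group with no read at all are lower limits against 3 counts over that group. The labels do not say that the 2 libraries of a group come from separate plants, nor which captured regions share a plant. Several regions may therefore come from 1 plant, p-values measure the spread between these samples, and they may be too small.

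The labels write a CNS line as Col(C24) or C24(Col) without saying which name is the nucleus. Allele reads settled the notation: organelle reads show which parent gave the cytoplasm, and the parent with about 2 of every 3 nuclear reads in endosperm, which holds 2 maternal genomes and 1 paternal, is the seed parent. By both measures the parent named first was the seed parent in the standard crosses. Col(C24) has Col cytoplasm and a C24 nucleus. A check added later took the median C24 share in windows of 5e+05 bases with at least 5 genes. In C24(Col) x Col(C24) embryo, 1 window lay -46.7 points from the library's median C24 share of 46.7%. In its endosperm 1 window lay 25.6 points off. Endosperm replicate 2 of the cross with Col(C24) named first had 2 windows over 20 points off, and Col x C24 endosperm replicate 2 had 1. Whether these segments have the labelled nucleus was not tested. The planned interactions between the sets had aligned CNS lines by the name outside the brackets, which sets opposite nuclei side by side. They are given as planned, together with the same tests aligned by nucleus, an alignment chosen after the allele reads were seen. The second kind of CNS hybrid is uneven, as labelled: its replicate 1 is Col x Col(C24) and its replicate 2 is C24(Col) x Col(C24). These replicates differ in cytoplasm and share nuclei by label, but not at every locus. At the gene MPK18 the embryo of replicate 1 had 86 Col and 98 C24 reads, and that of replicate 2 had 0 and 130.

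Parent-of-origin expression was tested per gene on the allele counts with edgeR's quasi-likelihood model. The library was a block, an allele term took up differences between Col and C24, and an offset set the maternal to paternal ratio to 2:1 in endosperm and 1:1 in embryo. Genes needed 10 allele reads in each library. Hybrids were set against the mean of the log levels of both selfed parents. The dosage slope relates the observed log2 ratio of the reciprocal hybrids to the ratio that 2 maternal and 1 paternal genome would give from the levels of the selfed parents, with 0.5 CPM added, over genes called between the parents; slope 1 is pure dosage, and genes are not independent replicates. Other splits of the samples into groups of the same sizes were fitted for comparisons with at least 3 samples per group.

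The 17 gene lists hold 242 entries for 222 genes: imprinted genes with maternal and with paternal expression, type I MADS genes, endosperm markers, seed size regulators, embryo markers, seed coat markers, nuclear photosynthesis genes, storage and oil genes, cell cycle genes, heat stress genes, wound and jasmonate genes, chromatin silencing genes, mitochondrial dysfunction genes, auxin biosynthesis genes, and the genes encoded in chloroplasts and in mitochondria. Of the entries, 229 carry the same symbol in the reference table. After poly-A selection, mitochondrial reads were 0.0608% to 2.51% of counts and chloroplast reads 0.0681% to 0.602%. Shifts of the 2 organelle lists thus cannot be told apart from differences in library composition. Lists were tested with camera in limma 3.58.1, at its preset correlation between genes and again with an estimated correlation, with Benjamini-Hochberg adjustment over the lists of a comparison. Named genes are the 5 with the largest change each way among called genes with a symbol, an average log2 CPM of at least 3 and no overlap between the libraries compared, and up to 4 members of each list with the smallest adjusted p. For parent of origin they are the 8 called genes with a symbol and the smallest p each way, and the imprinted genes with enough allele reads. Tests, lists, this rule and most alternatives were set before the data were examined; those added later are named as such.

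The tests were checked on simulated counts with known changes at the real means and depths. For the gene tests the spread was the fitted one, and changed genes were drawn from well-expressed genes only. The parent-of-origin and dosage simulations used an assumed spread, so their results hold for that spread. At a log2 change of 1, 2 and 3 the test recovered 5.97%, 65.7% and 93.9% of changed genes between selfed parents in endosperm, and 28.4%, 76.1% and 93.9% in embryo. For the reciprocal hybrids it recovered 5.97%, 76.1% and 87.9% in endosperm and 25.4%, 82.1% and 90.9% in embryo. The parent-of-origin test recovered 49% and 97% in endosperm, and 40% and 98% in embryo, at log2 ratios of 1 and 2. Simulated dosage slopes of 1 and 0 came out as 0.84 and -0.02.

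Groups share replicate numbers, so deviations of same-numbered libraries from their group means were correlated. All 6 pairs of groups lay above 0.1 in CNS endosperm (0.142 to 0.245) and in standard embryo (0.126 to 0.456), and there the numbers were taken to pair the libraries, from the data alone. In standard endosperm 4 of 6 pairs did (-0.0972 to 0.290) and in CNS embryo 5 of 6 (0.0235 to 0.580). Alternatives were DESeq2 1.42.0 in place of edgeR, its size factors or library totals in place of TMM, no filter or 50 counts in 2 libraries, the replicate number as a block, a fit of the compared groups alone, a fold threshold, organelle genes left out, each library left out in turn, and for allele reads other minimums, offsets and a rule on shares. No 2 libraries of a group agreed within sampling noise (chi-square per degree of freedom 23.5 to 176). Standard and CNS libraries also differ in depth and sample numbering, so a plain difference between the sets cannot be told apart from a difference between library batches.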

Results

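The series holds endosperm and embryo of selfed Col and C24 seeds, of both reciprocal hybrids, and of selfed and hybrid seeds of the CNS lines, with 2 libraries in each of 16 groups. Marker genes set the tissues apart: the embryo markers summed to 511 ± 117 CPM in endosperm and 1758 ± 147 CPM in embryo, and the endosperm markers to 1411 ± 207 and 145 ± 46.9 CPM (n = 16 libraries each). Seed coat markers were present in both, at 625 ± 288 CPM in endosperm and 312 ± 48.5 CPM in embryo. In Col x C24 seeds, C24 chloroplast and mitochondrial reads were 0.604% (exact 95% interval 0.243% to 1.24%) and 0.242% of organelle allele reads in endosperm. In C24 x Col seeds they were 99.4% to 99.9% over both tissues, so the parent named first is the mother. Nuclear allele reads fit this: C24 made up 30.8% of endosperm reads in either Col x C24 library, and 63.4% and 64.1% in C24 x Col.

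Which genes divide endosperm from embryo was asked first in the standard crosses. Endosperm held FIS2, a Polycomb gene that restrains its growth, the imprinted homeodomain gene HDG3, and SDC, an F-box gene silenced by DNA methylation elsewhere in the plant. It also held AGO3, an Argonaute that binds small RNAs, and SUC5, a sucrose transporter that feeds the embryo. Embryo held the patterning gene SCR, the auxin carrier PIN4, the auxin synthesis genes YUC4 and TAR2, and the organ growth genes KLU and ANT. Both the tannin gene BAN and the flavonoid gene LDOX of the seed coat were higher in endosperm. AP2, which limits seed size, was lower in endosperm, and DA1, which limits cell division, was higher.

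By edgeR, 15939 of 20235 genes were called, 7920 higher in endosperm and 8019 lower. FIS2 (chromosome 2, 14992565 to 14996756) rose from 0.772 ± 0.572 CPM in embryo to 58.2 ± 20.3 CPM in endosperm (log2 difference 6.47 ± 0.26, adjusted p = 6.7e-11, n = 8 libraries per tissue). PIN4 (chromosome 2, 180033 to 183764) was at 0.214 ± 0.313 CPM in endosperm and 18.8 ± 4.26 in embryo (-7.92 ± 0.36, adjusted p = 4.5e-10). SCR (chromosome 3, 20069987 to 20072878) was at 8.48 ± 2.47 and 107 ± 3.37 CPM (-3.71 ± 0.09, adjusted p = 5.4e-12). SK9, SK8 and SK7, members of a cluster of Skp1-like genes on chromosome 3, were among the largest increases, with SRP2 and AGO3, and HSFB4, HP6, scpl46 and XND1 were among the largest decreases. In CNS seeds 14984 of 21816 genes were called (7594 higher, 7390 lower). TFL1, LCR27, LCR16, SK9 and NAC099 led there, against PLT2 and PLT1 of the root stem cells, with MNP, ACL5 and BOP2. Of the genes called in both sets, 6920 were higher and 6851 lower in endosperm in both, and 2 differed in direction.

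Of 10 maternally expressed imprinted genes tested in the standard crosses 10 rose in endosperm (FIS2, FWA, SDC, ALN) and none fell (0), and of 10 paternally expressed genes 9 rose (VIM5, PKR2, HDG3, MYB3R2) and 1 was not called. Of 11 type I MADS genes 9 rose (PHE1, PHE2, AGL92, AGL23) and of 14 endosperm markers 13 rose and 1 fell. Of 27 embryo markers 23 fell (SCR, PDF2, ATML1, ABI3) and 3 rose, and of 23 seed coat markers 18 rose (MUM2, BAN, LDOX, TT10). Of 25 cell cycle genes 18 fell (MCM7, CYCA1;1) and 3 rose, of 13 storage and oil genes 10 fell (OLEO4, OLEO1) and 2 rose (WRI1 among them), and of 24 nuclear photosynthesis genes 17 fell (RCA) and 3 rose (LHCB2.1). Camera called these 9 lists, with adjusted p = 0.00019 for both imprinted lists and the endosperm markers, 0.0024 for type I MADS, 7.2e-06 for embryo markers, 0.0017 for seed coat, 0.0072 for cell cycle, 0.0499 for storage and 0.034 for photosynthesis. With an estimated correlation adjusted p was 0.06, 0.042, 0.328, 0.101, 0.453, 0.407, 0.453 and 0.703 in that order, with the imprinted lists equal. Adjusted over each list alone the counts were the same, but for photosynthesis with 4 higher. Of 82 chloroplast-encoded genes 48 rose and 14 fell (46 and 14 over the list alone; adjusted p = 0.0499, and 0.783 with an estimated correlation), and of 35 mitochondria-encoded genes 23 rose and 1 fell (0.0061 and 0.489).

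The other lists were not called by camera. Of 10 seed size regulators 6 fell (AP2, KLU, ANT) and 3 rose (DA1); of 19 chromatin silencing genes 11 fell (AGO4, DDM1, CLF) and 5 rose; of 12 heat stress genes 3 fell (HSFA2, HSP17.6II, HSP70; 2 over the list alone). Of 7 mitochondrial dysfunction genes 4 rose (ANAC017, ANAC013) and 1 fell (UPOX), of 6 auxin synthesis genes 2 rose (YUC10) and 3 fell (TAR2, YUC4, YUC1), and of 5 wound and jasmonate genes 2 rose (JAZ1, VSP2) and 2 fell (AOS, JAZ10). The wound list has a median log2 difference of 1.13 and a mean of 0.17, while its test points down. Camera adjusted p was 0.22, 0.12, 0.5, 0.132, 0.819 and 0.819 for these 6 lists. In CNS seeds all 12 tested maternally and all 10 paternally expressed imprinted genes rose (adjusted p = 0.00043 and 0.00054; 0.347 each with an estimated correlation), and of 65 mitochondria-encoded genes 4 rose and 13 fell.

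What differs between the endosperm of the 2 accessions was asked next. Col endosperm expressed far more of LCR48, a cysteine-rich peptide of the defensin type, of NF-YC5, a subunit of a CCAAT-binding factor, and of the paternally expressed genes PKR2, a chromatin remodeller, and ADM, a J-domain protein. C24 endosperm expressed more of FAE1, which elongates fatty acids for seed oil, of the albumin gene SESA1 and the oil body gene OLEO1, and of ABI3, the master regulator of seed maturation. The splicing factor gene SC35 and the gamete gene GEX3 were nearly silent in Col. Between the CNS lines FAE1, SESA1, ABI3 and GEX3 were again high with a C24 nucleus, now in Col cytoplasm, and LCR48, NF-YC5 and ADM with a Col nucleus, now in C24 cytoplasm.

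In standard endosperm edgeR called 1689 of 21210 genes, 1048 higher in Col and 641 higher in C24 (DESeq2 2632; 2649 in a fit of the compared groups alone). LCR48 (chromosome 3, 17858234 to 17858874) was at 2501 ± 206 CPM in Col and 0.582 ± 0.439 in C24 (12.01 ± 0.73, adjusted p = 2.6e-07, n = 2 libraries each). NF-YC5 (chromosome 5, 20560434 to 20561228) was at 53.3 ± 8.28 and 0.0958 ± 0.0566 CPM (9.09 ± 1.07, adjusted p = 0.00011), and PKR2 (chromosome 4, 15431350 to 15438678) at 83.9 ± 1.32 and 9.26 ± 4.26 (3.17 ± 0.43, adjusted p = 0.00033). FAE1 fell from 47.9 ± 28.9 CPM in C24 to 0.273 ± 0.386 in Col (-7.38 ± 1.26, adjusted p = 0.0021). GEX3 had no read in Col and 29.5 ± 0.11 CPM in C24, at least 173-fold (adjusted p = 0.0074). SADHU1-1, APD3 and RLP2 were also among the largest increases in Col, and GLP6 and SADHU3-2 among the largest in C24. The split between directions depends on scaling, as with library totals 781 genes were higher and 1286 lower. The count also depends on single libraries: it was 901 without Col replicate 1, 843 without Col replicate 2, 647 without C24 replicate 1 and 973 without C24 replicate 2, where the remaining library of the group is taken to vary like the other groups.

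Of 10 paternally expressed imprinted genes 4 rose in Col (PKR2, ADM, TAR1, PHE2; 6 over the list alone) and of 14 type I MADS genes 5 rose (AGL91, AGL40, AGL61, PHE2; 9 over the list alone), each with camera adjusted p = 0.00026 (0.24 and 0.552 with an estimated correlation). Of 11 storage genes 5 fell (OLEO1, SESA1, WRI1, FAE1; 6 over the list alone; adjusted p = 0.00026, and 0.552 with an estimated correlation). Of 12 maternally expressed imprinted genes 3 rose (BMI1C, NRPD1, HDG8; 4 and 2 lower over the list alone; adjusted p = 0.645). LHCB1.2 fell and LHCB2.1 rose among 24 photosynthesis genes (1 and 2 over the list alone), a list with adjusted p = 0.00026 downward (0.865 with an estimated correlation). Of 82 chloroplast-encoded genes 15 rose and 1 fell (29 and 1 over the list alone; adjusted p = 3.2e-08, and 0.552 with an estimated correlation).

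Between the CNS lines edgeR called 1676 genes, 777 higher and 899 lower in Col(C24), which has the C24 nucleus. With replicate number as a block the count was 2849, with DESeq2 2857, and in a fit of the compared groups alone 389. LCR48 was at 0.0917 ± 0.13 CPM in Col(C24) and fell there by a log2 difference of -13.94 ± 0.80 (adjusted p = 1.2e-07, n = 2 libraries each). CYP705A32, a cytochrome P450 gene, had 63.8 ± 7.17 CPM in Col(C24) and no read in C24(Col), at least 1167-fold (adjusted p = 1.4e-05). SADHU1-1 had no read in Col(C24), at least 1919-fold lower (adjusted p = 3.1e-07), and SADHU1-3, GLP6, SADHU3-2, APD3 and SCRL15 completed the largest changes. MEA, the core Polycomb gene of endosperm, fell to 0.0262 ± 0.037 CPM in Col(C24) from 5.4 ± 3.26 (-7.37 ± 1.35, adjusted p = 0.0035). Without C24(Col) replicate 2 the count was 734. Of the 1008 genes called in both sets, 1006 followed the nucleus (67.9 shared by chance if calls in this single fit were independent). Over all genes 74.7% had the same sign by nucleus.

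In that comparison 4 of 12 maternally expressed imprinted genes fell with the C24 nucleus (BMI1C, MEA, NRPD1, FWA; 5 over the list alone; camera adjusted p = 0.0053, and 0.313 with an estimated correlation). Of 10 paternally expressed genes 2 fell (ADM, TAR1; 7 over the list alone; 0.00015 and 0.218), and of 14 type I MADS genes 2 fell (AGL35, AGL80; 5 over the list alone; 0.00011 and 0.313). Of 11 storage genes 2 rose (FAE1, SESA1; 3 over the list alone; 0.0451 and 0.482). Of 24 photosynthesis genes 2 rose (LHCB1.2, RBCS2B; 3 and 1 lower over the list alone) with adjusted p = 0.062, or 0.0035 with the replicate block (0.762 with an estimated correlation). RBCS2B turned direction without Col(C24) replicate 2, so its rise rests on 1 library. Of 82 chloroplast-encoded genes 21 fell (48 over the list alone; 6.8e-21 and 0.222) and of 56 mitochondria-encoded genes 3 fell (2 over the list alone; 4e-10 and 0.313).

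How the direction of the cross changes hybrid endosperm was asked with the reciprocal hybrids. A Col mother gave more of CYSA, a cysteine protease inhibitor, PP2-B1, an F-box protein of the phloem lectin type, GAE1, which makes precursors of pectin, ATG8D of autophagy and ADF6, which cuts actin filaments. A C24 mother gave more of NF-YC5, of LCR8, another defensin-like peptide, of BNQ2, a helix-loop-helix protein of light signalling, of URH1, a nucleoside hydrolase, and of CYP79A2, which starts benzyl glucosinolates. NF-YC5, silent in selfed C24 endosperm, was thus high when Col was the father, and low when Col was the mother. In CNS seeds NF-YC5, BNQ2 and LCR8 were again higher with a C24-nucleus mother, with SMP1 of seed maturation and the stress regulator NAC046. JLO, a boundary gene of the LOB family, the proline transporter gene PROT2, the steroid dehydrogenase gene HSD2, SADHU1-1 and the callose synthase gene GSL05 were higher with a Col-nucleus mother. Allele reads of JLO were 99.8% ± 0.32% maternal in CNS endosperm (n = 4 libraries). For JLO, seed coat RNA of the mother thus cannot be told apart from expression in endosperm.

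In the standard crosses edgeR called 47 genes, 19 higher and 28 lower in Col x C24 (DESeq2 334; 114 in a fit of the compared groups alone). NF-YC5 was at 3.11 ± 1.97 CPM in Col x C24 and 60.2 ± 1.85 in C24 x Col (-4.21 ± 0.74, adjusted p = 0.031, n = 2 libraries each), LCR8 (chromosome 3, 22641713 to 22642182) at 18.1 ± 1.57 and 85.2 ± 7.07 (-2.24 ± 0.29, adjusted p = 0.0085), and CYSA at 35.3 ± 5.9 and 6.72 ± 1.43 (2.38 ± 0.39, adjusted p = 0.022). The count was 3 and 15 without replicate 1 and 2 of Col x C24, and 4 and 19 without replicate 1 and 2 of C24 x Col, so single genes near the limit are uncertain. No list but the organelle lists was called, and camera with an estimated correlation gave each of these adjusted p = 0.815. Of 82 chloroplast-encoded genes 1 rose and 1 fell (18 and 2 over the list alone, camera adjusted p = 2.2e-07). Of 56 mitochondria-encoded genes none (0) was called (4 higher over the list alone, camera adjusted p = 2.7e-07). Mitochondrial reads were 1.13% and 0.509% of counts in replicate 1 and 2 of Col x C24, and 0.181% and 0.261% in C24 x Col. Reads without a feature were 14.3% and 9.49%, and 6.60% and 8.24%, so library composition cannot be told apart from organelle expression.

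In CNS seeds edgeR called 69 genes, 49 higher and 20 lower with the C24-nucleus mother, 499 with the replicate block, 583 with DESeq2 and 9 in a fit of the compared groups alone. BNQ2 (chromosome 5, 4921243 to 4922812) was at 183 ± 53.1 CPM with the C24-nucleus mother and 20.7 ± 4.27 with the Col-nucleus mother (3.15 ± 0.41, adjusted p = 0.008, n = 2 libraries each), and JLO (chromosome 4, 89908 to 92255) at 28.8 ± 3.11 and 65.9 ± 11 (-1.19 ± 0.22, adjusted p = 0.037). Of the crosses with Col(C24) named second, the count was 21 without replicate 1 and 19 without replicate 2; of those with it named first, 253 without replicate 1 and 6 without replicate 2. Heat stress genes had no call among 12 (0; also 0 over the list alone) but were shifted upward as a list (camera adjusted p = 0.00011, and 0.712 with an estimated correlation), with sums of 2999.8 and 1320.8 CPM against 578 and 768 in replicate 1 and 2, as were type I MADS (0.0073) and photosynthesis genes (0.01). Embryo markers (0.0073), cell cycle (0.01), chromatin silencing (0.01), chloroplast-encoded (0.00057) and mitochondria-encoded genes (0.0025) were shifted downward, none with an estimated correlation. Of the 47 genes, 46 moved with the nucleus in the same direction in CNS seeds, against 68.5% of all genes. In both sets 30 genes were called, 8 higher and 22 lower with a Col-nucleus mother. Chance would share 0.0826 if calls were independent, but the 2 tests come from a single fit with 1 spread per gene.

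**Figure D1:**
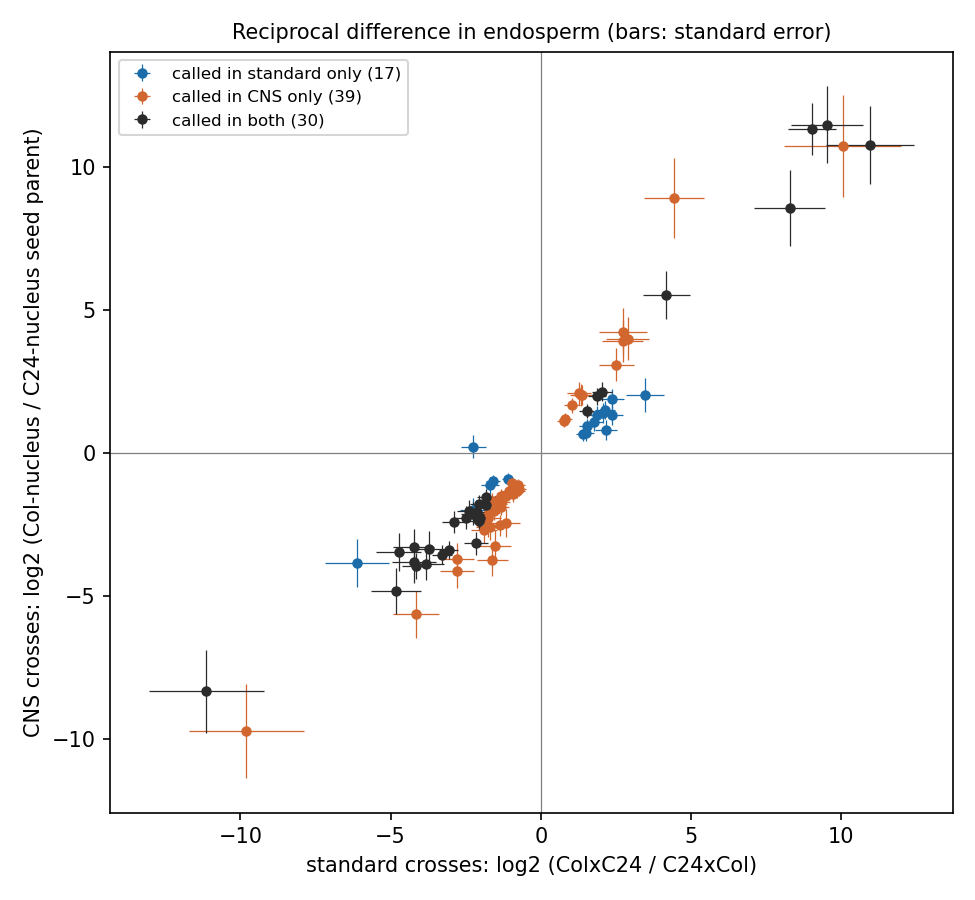
Reciprocal log2 differences in endosperm of standard and CNS hybrids, aligned by nucleus, with standard errors; 30 genes were called in both sets, 17 in the standard crosses alone and 39 in CNS crosses alone.

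Whether cytoplasm changes the reciprocal difference was asked with interactions between the sets. As planned, by the name outside the brackets, edgeR called 710 genes in endosperm (472 higher, 238 lower), and 4405 for the selfed lines (2110 higher, 2295 lower), because that alignment sets opposite nuclei side by side. Aligned by nucleus, the alignment chosen later, the reciprocal interaction had 0 calls in endosperm (edgeR; 293 genes with unadjusted p under 0.05; DESeq2 called 1), and the interaction between selfed lines had 1 (740 unadjusted; DESeq2 17). In embryo the planned reciprocal interaction had 0 calls (edgeR; 846 unadjusted; DESeq2 21) and the nucleus-matched one 0 (270 unadjusted; DESeq2 2). For selfed embryos they had 2174 (1139 higher, 1035 lower) and 7 (2 higher, 5 lower; 684 unadjusted; DESeq2 35). With the replicate block each of these embryo counts was higher, as given with the dependence on processing. Left-out libraries moved the counts without the block. The 710 became 251 and 442 without Col x C24 replicate 1 and 2, 248 and 471 without those of C24 x Col, 385 without replicate 2 of the CNS cross with Col(C24) named second, and 239 without replicate 2 of the cross with it named first. The 4405 became 2572 without C24 replicate 1 and 2924 without C24(Col) replicate 2, and the 1 became 2 without Col replicate 2, 41 without C24(Col) replicate 1 and 5 without Col(C24) replicate 1. In embryo the 2174 became 1426 without Col replicate 1 and 1364 without C24(Col) replicate 2, and the 7 became 3 and 4 without Col replicate 1 and 2, and 3 without C24 replicate 2 or C24(Col) replicate 2. The test has little reach here: simulated nucleus-matched changes of log2 1, 2 and 3 were recovered at 2.99%, 34.3% and 78.8% for reciprocal endosperm and 5.97%, 62.7% and 83.3% for reciprocal embryo. The nucleus-matched reciprocal test also does not swap cytoplasm cleanly. In its CNS group with a Col-nucleus mother, replicate 1 has Col cytoplasm, as Col x C24 has, and replicate 2 has C24 cytoplasm. NF-YC5, BNQ2 and LCR8 were not called for a change between the sets.

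The nucleus-matched interactions shifted some lists without single calls. In selfed endosperm heat stress genes were up (camera adjusted p = 1.4e-05, and 0.456 with an estimated correlation; median log2 3.46). Their summed levels lay far apart within groups: 1239.5 and 282 CPM in replicate 1 and 2 of Col, 688 and 2027 in C24, 1059.8 and 274 in C24(Col), and 758 and 178 in Col(C24). Cell cycle (0.00039), chloroplast-encoded (0.00049), maternally expressed imprinted (0.0058), chromatin silencing (0.0058) and mitochondria-encoded genes (0.035) were shifted too, none with an estimated correlation. In reciprocal endosperm heat stress (0.01), cell cycle (0.011), embryo markers (0.023), seed size regulators (0.026) and mitochondria-encoded genes (0.023; median -0.34, mean 0.33) were shifted, none with an estimated correlation. In selfed embryo the 19 chromatin silencing genes were up without a single call (0.00049, and 0.041 with an estimated correlation), and heat stress genes too (6.8e-06 and 0.952), whose sums were 1801.5 and 220.5 CPM in replicate 1 and 2 of Col, 1039.8 and 6479 in C24, 1883 and 344 in C24(Col), and 1661.6 and 109.9 in Col(C24). In reciprocal embryo photosynthesis (0.00041) and storage genes (0.0032) were down and chloroplast-encoded (3.7e-13) and mitochondria-encoded genes (0.014) up, each 0.758 with an estimated correlation. Over all comparisons 106 of 340 list tests were called and 2 stayed called with an estimated correlation: endosperm markers between tissues in the standard crosses, and chromatin silencing genes in the selfed embryo interaction.

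Whether hybrid endosperm departs from the mean of its parents was asked in the standard crosses. CKI1, a histidine kinase needed for the central cell, SPX1, a phosphate sensor, the invertase gene A/N-InvC, the phosphatase gene PFA-DSP3, the flavonoid gene UGT78D2 and the mucilage gene MUM2 were above the log mean of selfed Col and C24. In embryo the flowering repressor FLC was above it. In the edgeR test no gene was below the log mean in either tissue. Against the arithmetic mean of the parents, 3 of the 152 endosperm calls and 0 of the 94 embryo calls stayed, and none of the genes named here. The endosperm genes named here still lay above that mean, by log2 1.09 (PFA-DSP3) to 2.18 (CKI1). That test has little reach: at an assumed spread it recovered 3% of simulated rises of log2 1 and 82% of log2 2.

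By edgeR 152 genes were above the log mean in endosperm and 0 below, out of 1422 with unadjusted p under 0.05 (DESeq2 351 and 8; 277 called in a fit of the compared groups alone). CKI1 was at 117 ± 94.7 CPM in hybrids and 25.8 ± 11.4 in selfed parents (1.95 ± 0.32, adjusted p = 0.0076, n = 4 libraries each). The count was 73 without C24 replicate 1, 79 without Col replicate 2, 92 without C24 x Col replicate 1 and 99 without Col x C24 replicate 2. Embryo markers (camera adjusted p = 1e-06), photosynthesis genes (3.9e-07) and chloroplast-encoded genes (0.012) were shifted downward as lists without a call (0.68 with an estimated correlation). In embryo 94 genes were above and 0 below (432 unadjusted; DESeq2 131 and 0; replicate block 116 and 1). FLC (chromosome 5, 3173382 to 3179448) was at 193 ± 27.6 CPM in hybrids and 98.3 ± 74.6 in parents (1.38 ± 0.15, adjusted p = 0.0005, n = 4 libraries each). The count was 59 and 60 without Col replicate 1 and 2, and 57 without C24 replicate 1. Photosynthesis and heat stress genes were up as lists (0.0037 each) and mitochondria-encoded genes down (0.0041), each 0.958 with an estimated correlation. With the replicate block embryo markers (0.136 to 0.018), storage (0.333 to 0.0063) and chloroplast-encoded genes (0.136 to 0.00095) changed to called, each 0.958 with an estimated correlation and no block.

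Which genes are expressed from 1 parent's alleles was asked with the allele reads. In endosperm the known maternally expressed genes FIS2, SDC, BMI1C and HDG9 were maternal, and the paternally expressed genes VIM5, PHE1, PKR2, YUC10 and HDG3 were paternal. GILT, a thiol reductase gene, JLO, NF-YC12, a further CCAAT factor subunit, MLP28 and, in CNS seeds, LTP6 were almost wholly maternal, while ORTHL and ULP1D, which act in DNA methylation and SUMO removal, AAE12, RBP47C' and the phosphatase gene BSU1 were paternal. GTC2 leaned to the paternal side, with 25.1% maternal reads with a Col mother and 52.1% with a C24 mother. BAN and LDOX, on the seed coat list, were maternal as well. Seed coat markers were present in the endosperm libraries, and the 11 tested in standard endosperm had a median maternal share of 97.9%. For the maternal calls in endosperm of both sets, these shares cannot tell seed coat RNA apart from maternal expression in endosperm. MYB3R2, listed as paternally expressed, was maternal here in both sets. MPC followed the accession rather than the parent: 5.26% of its reads were maternal with a Col mother, and all were maternal with a C24 mother.

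The median gene had 67.5% ± 2.45% maternal reads in standard endosperm and 67.1% ± 3.38% in CNS endosperm (n = 4 libraries each). By edgeR 334 of 8271 genes departed from 2:1 in standard endosperm, 174 to the maternal and 160 to the paternal side (a rule on shares counted 166), and 213 of 9219 in CNS endosperm (109 and 104). SDC reads were 99.8% ± 0.04% maternal (adjusted p = 2.3e-10, n = 4 libraries), FIS2 99.5% ± 0.675% (adjusted p = 4.7e-06), VIM5 3.97% ± 1.76% (adjusted p = 2.3e-10), PHE1 5.46% ± 4.63% (adjusted p = 2.2e-08) and HDG3 36.7% ± 8.33% (adjusted p = 6.5e-06). HDG9 was 96.9% maternal with a C24 mother and 65.7% with a Col mother. MYB3R2 was 97.8% ± 3.07% maternal (adjusted p = 1.3e-05). NRPD1, PHE2, HDG8, MPC, ALN and FH5 were not called. The standard count was 1143 without Col x C24 replicate 1, 164 without C24 x Col replicate 1 and 118 without C24 x Col replicate 2, and the CNS count was 100 without replicate 2 of the cross with Col(C24) named first.

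**Figure D2:**
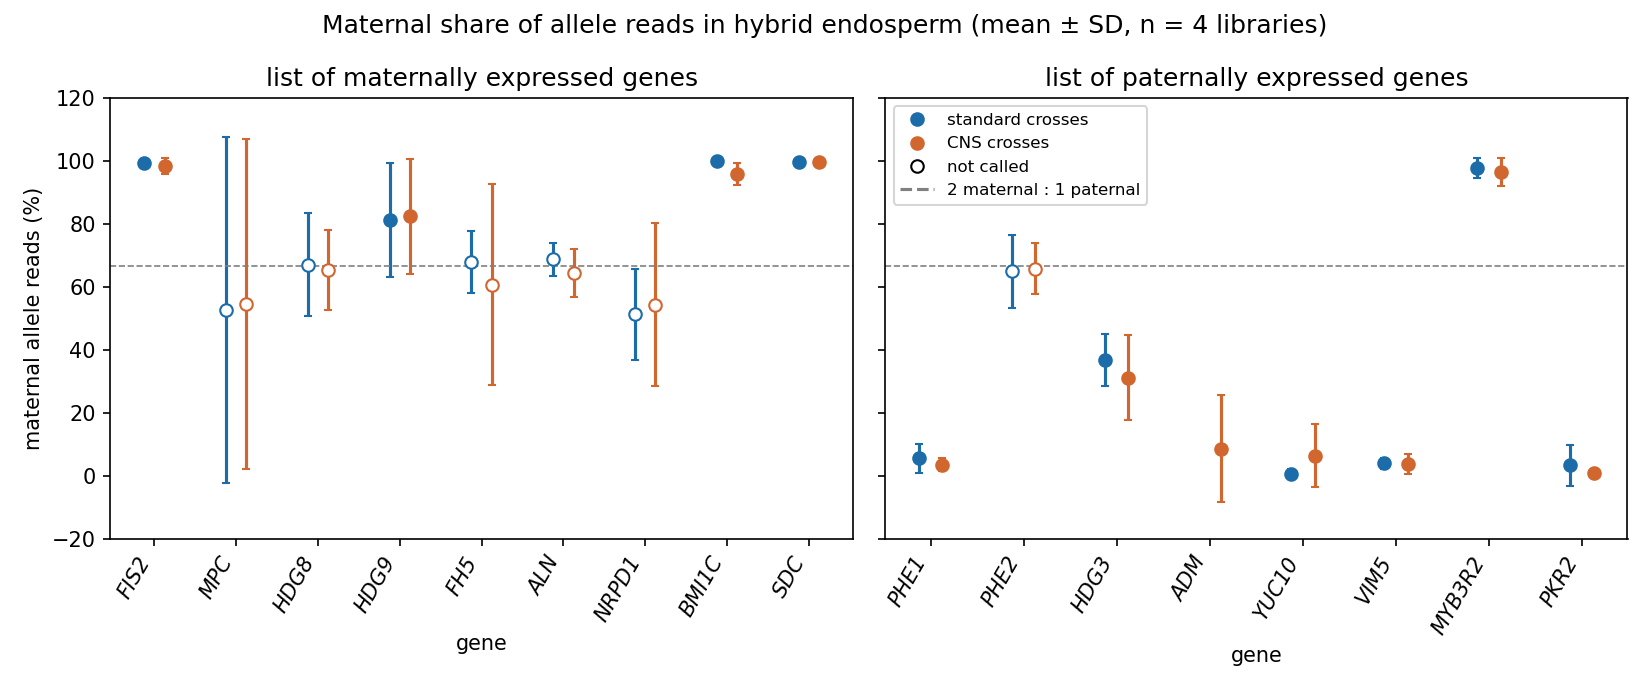
Maternal share of allele reads in endosperm for imprinted genes (mean ± SD, n = 4 libraries), standard crosses in blue and CNS crosses in orange; open symbols were not called, and the dashed line is the 2:1 dosage of endosperm.

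Of 9 maternally expressed genes on the list with enough reads in standard endosperm 4 were maternal (4 and 1 paternal over the list alone), and of 7 paternally expressed genes 5 were paternal and 1 maternal. In CNS endosperm these were 4 of 9, and 6 of 8 with 1 maternal. Of the type I MADS genes 2 of 3 and 3 of 4 were paternal (PHE1, AGL86 in CNS seeds). Of 11 seed coat markers 9 were maternal in standard endosperm (11 over the list alone) and 6 of 8 in CNS endosperm (7 over the list alone). Between the sets 91 maternal and 89 paternal genes were shared, against 1.88 and 1.89 by chance. A test of whether the share itself changed with the set called 0 of 7913 genes (edgeR; 257 with unadjusted p under 0.05; a rule on the shares counted 3), and PHE1, HDG3, FIS2 and SDC gave adjusted p = 1 there. Of 17 genes with a reciprocal difference and enough allele reads 5 were also called by parent of origin in the standard crosses (0.69 by chance; Fisher's exact p = 0.00044), and 8 of 34 in CNS crosses, JLO and NF-YC5 among them (0.787 by chance; Fisher's exact p = 7.8e-07). On the maternal side lay 4 of those 5 and 6 of those 8, for which seed coat RNA cannot be told apart from endosperm expression. Of the 47 standard genes 34 were also called between the parents, 23 of them in the same direction, and of the 69 CNS genes 40, with 35 in the same direction.

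In embryo the same test was read against 1:1. VIM5, which maintains DNA methylation, the microRNA gene MIR863 and the kinase gene MKK5 were paternal. VIM5 had 3.20 CPM in hybrid embryos, 4.05% of its level in endosperm. The imprinted and type I MADS genes used as markers of endosperm RNA had a median of 2.56% and an upper quartile of 3.51%. VIM5 and the maternal call SDC are themselves among these 28 markers. For VIM5, endosperm RNA thus cannot be told apart from paternal expression in embryo. GILT, JLO, BAN, LDOX, SDC and the protease gene DELTA-VPE of the seed coat were strongly maternal. Leaning to the maternal side were ALE1, a subtilisin protease that acts between endosperm and embryo, SBTI1.1, another subtilisin protease, and UGD3, which makes wall sugars. By edgeR 102 of 9654 genes were called in standard embryo, 97 maternal and 5 paternal (a rule on shares counted 13), and 6 of 9794 in CNS embryo (5 and 1), where GILT had maternal reads only and ALE1 had 70.3% ± 9.01% (adjusted p = 0.014, n = 4 libraries). ALE1 reads were 66.4% ± 5.55% maternal in standard embryo (adjusted p = 8.5e-12, n = 4 libraries), SBTI1.1 67.7% ± 0.829% (adjusted p = 1.9e-09), GILT 98.1% ± 3.51% (adjusted p = 3.3e-23) and VIM5 6.75% ± 9.8% (adjusted p = 6.8e-07). The standard count was 53 and 38 without replicate 1 and 2 of C24 x Col, and 56 without Col x C24 replicate 2. The CNS count was 514 without replicate 1 of the cross with Col(C24) named second, and 2 and 1 without replicate 1 and 2 of the cross with it named first.

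Whether gene dosage sets the reciprocal difference was asked with the genes called between the parents. A gene such as LCR48, expressed from Col alleles alone, should be higher when Col is the mother and gives 2 genomes, while NF-YC5 moved the other way. Over 1689 genes the slope on the dosage expectation was 0.56 in endosperm (0.52 and 0.60 in replicate 1 and 2, r = 0.34), against 1 for pure dosage. Simulated pure dosage gave 0.84, at parental differences of log2 2 and an assumed spread. The fit itself can thus fall short of 1, by an amount not known for the real genes. In embryo, where both parents give 1 genome and the same scale predicts no difference, the slope was 0.15 over 805 genes (0.11 and 0.20; r = 0.25). The order of the tissues depends on the genes used: at an average log2 CPM of at least 5 the slope was 0.23 in endosperm (629 genes) and 0.34 in embryo (154 genes), and over all genes tested it was 0.41 and -0.0278. Without C24 replicate 1 or Col replicate 2 the endosperm slope was 0.71 and 0.73, and without Col replicate 1 the embryo slope was 0.08.

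**Figure D3:**
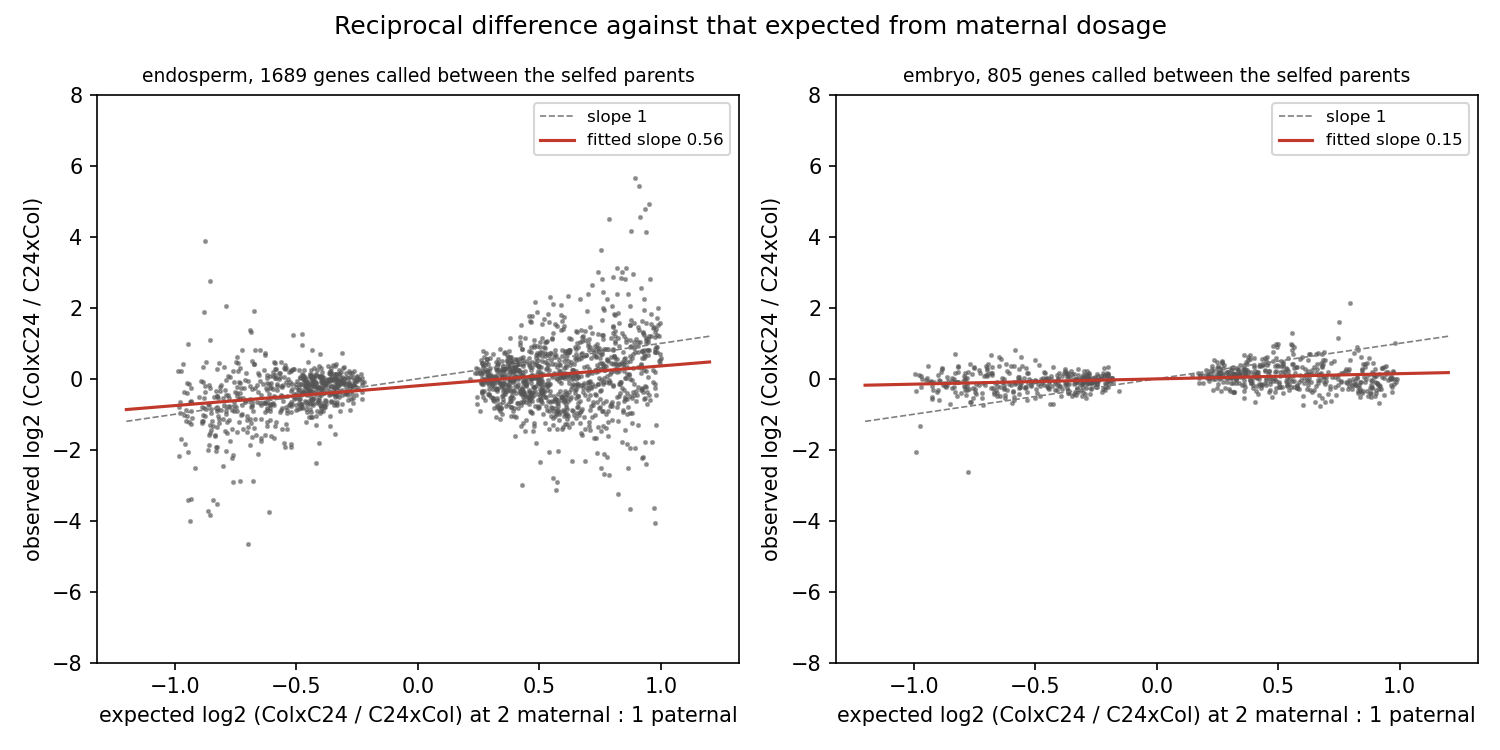
Observed log2 ratio of Col x C24 to C24 x Col against the ratio that 2 maternal and 1 paternal genome would give from the selfed parents, for genes called between the parents, in endosperm and embryo.

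What differs between Col and C24 embryos was asked with the selfed seeds. Col embryos expressed more of MAF1, a relative of the flowering repressor FLC, of ATS3, an embryo protein, of ANAC013, which answers mitochondrial failure, and of the retroelements SADHU1-1 and Sadhu4-2. C24 embryos expressed more of the albumin gene SESA1, the antenna gene LHCB1.2, the Rubisco activase gene RCA, the auxin synthesis gene TAR2, the peroxiredoxin gene TPX2, and SC35. In CNS embryos MAF1, ATS3 and ANAC013 were high with a Col nucleus and SESA1, LHCB1.2, RCA, TAR2 and TPX2 with a C24 nucleus. The oil body genes OLEO1 and OLEO2, the oil regulator WRI1 and the jasmonate gene AOS were also higher with a C24 nucleus there, as was the flavonoid gene TT4, while VRN2 of the Polycomb complex was lower.

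By edgeR 805 of 19942 genes were called in standard embryo, 449 higher in Col and 356 lower, 2428 with the replicate block and 1476 with DESeq2. MAF1 (chromosome 1, 28955483 to 28960234) was at 24.2 ± 0.713 CPM in Col and 0.9 ± 0.401 in C24 (4.75 ± 0.27, adjusted p = 1.7e-06, n = 2 libraries each), and SESA1 at 6.58 ± 1.49 and 114 ± 7.44 (-4.12 ± 0.54, adjusted p = 0.00055). SADHU1-1 had 61.4 ± 14.4 CPM in Col and no read in C24, at least 711-fold (adjusted p = 3.3e-05). DUF9 was also among the largest increases, and SADHU3-2 and SADHU1-3 among the largest decreases. The count was 425 and 441 without Col replicate 1 and 2, and 527 and 430 without C24 replicate 1 and 2. Between CNS lines 900 genes were called, 469 higher and 431 lower in Col(C24) (DESeq2 1701; 287 in a fit of the compared groups alone), with 558 left without Col(C24) replicate 1 and 507 without C24(Col) replicate 2. MAF1 was at 1.49 ± 0.0631 CPM there and 33.4 ± 4.41 in C24(Col) (-4.48 ± 0.25, adjusted p = 6.1e-07), and MRD1 at 58.3 ± 9.91 and 0.878 ± 0.655 (6.10 ± 0.59, adjusted p = 3.7e-05). Of 564 genes called in both sets, 563 followed the nucleus (18.1 shared by chance if calls in this single fit were independent). Over all genes 69.6% had the same sign by nucleus.

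Of 24 photosynthesis genes 3 fell in Col (LHCB1.2, RCA, LHCA2; 5 over the list alone; camera adjusted p = 4.5e-11, and 0.532 with an estimated correlation), and 3 rose with the C24 nucleus in CNS embryos (9 over the list alone; 4e-08 and 0.522). Of 12 storage genes 1 fell in Col (SESA1; 3 over the list alone; 1.1e-05 and 0.646), and 4 rose with the C24 nucleus (11 over the list alone; 6.1e-07 and 0.618). Chloroplast-encoded (1.1e-05) and mitochondria-encoded genes (0.011) were up in Col without a call, and heat stress genes down (0.02), with adjusted p = 0.646, 0.664 and 0.646 with an estimated correlation. With the replicate block 5 lists changed to called: maternally (0.0876 to 0.028) and paternally expressed imprinted genes (0.0507 to 0.0094), type I MADS (0.0502 to 0.017), endosperm markers (0.0559 to 0.023) and seed coat markers (0.0688 to 0.042), each 0.646 with an estimated correlation and no block. In CNS embryos chromatin silencing genes were down (1 of 19 called, VRN2; 0.013 and 0.238), and 1 of 61 mitochondria-encoded genes fell (3.7e-09 and 0.694).

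Whether the direction of the cross matters in embryo was asked last. FTM1, a stearoyl desaturase gene of the shoot meristem, was higher with a Col mother, and no other gene was called. FTM1 (chromosome 1, 16577521 to 16579722) was at 71.0 ± 15.7 CPM in Col x C24 and 18.8 ± 2.24 in C24 x Col (edgeR, 1.92 ± 0.22, adjusted p = 0.022, n = 2 libraries each; 319 genes with unadjusted p under 0.05), and the replicate block called 2 genes, while library totals and a fit of the compared groups alone called 0. In CNS embryos FTM1 had 82.4 ± 13.0 CPM with a Col-nucleus mother and 86.4 ± 8.2 with a C24-nucleus mother, a difference of the opposite sign that was not called. The count was 0 without Col x C24 replicate 1 and without either replicate of C24 x Col. Photosynthesis (camera adjusted p = 0.019) and type I MADS genes (0.0495, or 0.062 with the replicate block) were down as lists, seed coat markers up (0.0495), each 0.976 with an estimated correlation, and storage genes went from 0.161 to 0.029 with the block (0.976 with an estimated correlation and no block). In CNS embryos 0 genes were called (edgeR; 660 with unadjusted p under 0.05; DESeq2 15). Photosynthesis genes were up there with a C24-nucleus mother (0 called; 3 over the list alone; 2.5e-10, and 0.623 with an estimated correlation), as were heat stress genes (0.017 and 0.882), and chloroplast-encoded (1.9e-18 and 0.797) and mitochondria-encoded genes (3.8e-10 and 0.797) were down.

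**Figure D4:**
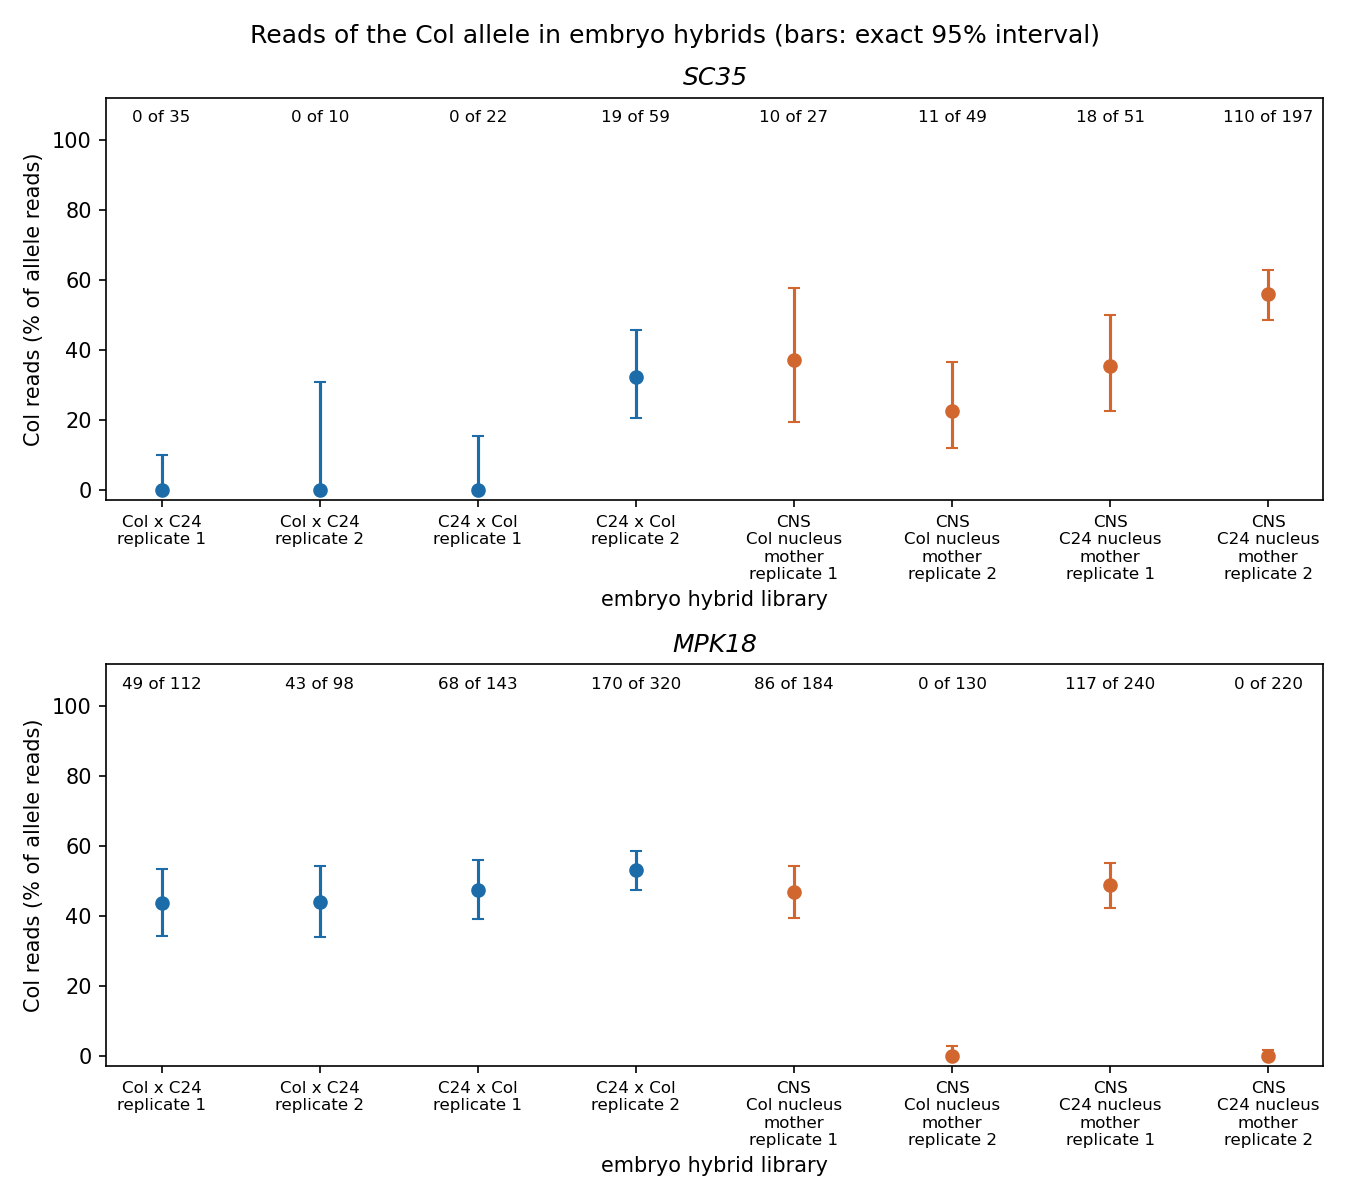
Share of Col reads at SC35 and MPK18 in each hybrid embryo library, by cross and replicate.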

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

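Every test of an explanation in this part was chosen after the result was seen. SC35, a splicing factor gene, stood out because the difference of the selfed lines with a Col nucleus from those with a C24 nucleus changed between the sets: aligned by nucleus the change was 8.01 log2 in endosperm, the 1 call there, and 9.29 in embryo. MPK18, a kinase gene that acts on microtubules, changed by -3.55 in embryo and MRD1, a gene close to it on chromosome 1 (19963047 and 19970334), by -6.93. The protease gene SBTI1.1 changed by -2.04, AT1G28700 by -1.76, AT4G08093 by 7.92 and AT5G03810 by -6.21, which completes the 7 embryo calls. The planned interactions, with 710 and 4405 calls in endosperm and 2174 in embryo for selfed lines, differ between the sets because their alignment opposes the nuclei.

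The first pattern weighed is SC35, at 0.341 ± 0.0191 CPM in selfed Col endosperm and 94.2 ± 10.9 in C24(Col), which has a Col nucleus too, and MPK18. Cytoplasm and Col plants that differ at the locus were the explanations tried. Each test has a single library on at least 1 side and its p covers the sampling of reads only. Both explanations stay open for SC35 and for MPK18, where the cytoplasm in which a parental line had been kept was not tested. At MPK18 the reads argue only against the cytoplasm of the seed itself as the sole cause of missing Col reads. Single libraries with the same seed cytoplasm held or lacked them. With C24 cytoplasm, C24 x Col embryos had 68 Col to 75 C24 reads and 170 to 150, against 0 to 130 in C24(Col) x Col(C24). Col reads at SC35 were 0 of 45 in Col x C24 embryos and 10 of 27 in replicate 1 of the CNS cross with the same cytoplasm and a Col seed parent (Fisher's exact p = 1.6e-05), and 0 of 22 and 19 of 59 in the replicates of C24 x Col embryos (Fisher's exact p = 0.0011), while the cross with Col(C24) named first had 110 of 197 in embryo but 0 of 30 in endosperm of its replicate 2. At MPK18 replicates 1 and 2 of the cross with Col(C24) named first, both with Col cytoplasm, had 117 of 240 and 0 of 220 Col reads in embryo (Fisher's exact p = 1.1e-41), and 42 of 127 and 0 of 107 in endosperm (Fisher's exact p = 2.4e-13). C24(Col) x Col(C24), which is replicate 2 of the other CNS cross, also had 0 of 130 in embryo, and 7 of 63 in endosperm, and whether C24(Col) was the father in replicate 2 of the first cross was not tested, as pollen passes on no organelle reads.

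The second pattern is the set of maternal calls in the embryo, such as ALE1 and SBTI1.1, of which 94 of 97 were higher in endosperm, against 30.6% of 9557 other genes (Fisher's exact p = 7e-44). An even carry-over of endosperm RNA is argued against as the whole cause: 52 of the 96 calls with enough endosperm reads stayed called when every gene was tested (edgeR) against the share such a carry-over would give at 3.51% of the endosperm level, the upper quartile of 28 markers, and 57 at their median of 2.56%. The other 44 stay open, and at the highest marker, 43.1%, 18 calls were kept while 2755 genes turned paternal, so that level is too high for an even carry-over. RNA of endosperm that lies against the embryo cannot be told apart from maternal expression, as 12 of the 87 measured calls with a share under 85% exceeded the share of the same gene in endosperm by more than 1 SD. Seed coat RNA stays open for the 9 calls with a share of 85% or more, since 9 had such a share in endosperm too, and maternal expression within the embryo was not tested.

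The third pattern is hybrids above the log mean of the parents, a mean that lies below additive expression wherever 1 parent is near 0, and the called genes differed between the parents by a median log2 of 7.94 in endosperm and 9.27 in embryo. Against the arithmetic mean of the parents 3 of 152 genes stayed called in endosperm (LCR8, AT1G07690 and AT5G39230) and 0 of 94 in embryo. The median log2 ratio to the arithmetic mean was 0.54 in endosperm, which leaves expression above additivity possible there, and 0.0185 in embryo, which argues against it for the genes as a set. Single genes part from this: CKI1 lay above the arithmetic mean by 2.18 ± 0.34 log2 (edgeR fit, adjusted p = 0.067) and FLC by 0.98 ± 0.16 (adjusted p = 0.392). From the log mean they differed by 1.95 ± 0.32 and 1.38 ± 0.15. The arithmetic test also averages the hybrids arithmetically, so the part due to the parents' mean cannot be read from these values. SPX1, A/N-InvC, PFA-DSP3, UGT78D2 and MUM2 lay 1.09 to 1.41 log2 above the arithmetic mean, and 120 of the 152 endosperm genes lay above it. That test recovered 3% of simulated rises of log2 1. In simulated additive genes with parents only 8-fold apart, far less than in the called genes, the log mean gave 20 calls of 2000 and the arithmetic mean 1.

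Where a comparison has at least 3 samples per group, other splits of the samples were fitted in the same way. For the tissues 1 of 100 splits drawn from 6435, the real one, reached its 15790 calls in the standard crosses and its 15292 in CNS crosses, with 0 as the highest other count in both. For hybrids against parents, the real split of the 8 samples gave 0 calls when cross was left out of the fit. Any split reaches 0 calls, as 35 of 35 did, so these splits decide nothing. The highest counts were 179 in endosperm, for the split by Col and C24 seed parent, and 1219 in embryo, for the split by replicate number. The test for a change of parental share also had 0 calls, which 18 of 18 splits reach by construction, so the splits cannot judge it. The highest other count was 1.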

How the results depend on the processing

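The arithmetic mean, the opposite and nucleus-matched alignments and the block by cross and number were chosen after the data were seen. DESeq2's size factors, 50 counts in 2 libraries and organelle genes left out kept all 20 counts within 1.5 times; so did 5 or 20 allele reads and an offset from the observed ratio for the 5 counts by parent of origin. DESeq2 kept 6 and moved 14, no filter kept 8 and moved 12, and leaving out a library kept 125 of 184. Of 486 results for named genes 319 kept direction and side of the threshold throughout, and 406 kept them but for left-out libraries. The cause was not tested unless named. Left-out libraries leave 1 library in a group, assumed to vary like the others. Depth limits single genes: 3 counts are the floor for folds, and libraries of standard endosperm are the shallowest.

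With DESeq2 the endosperm counts were 2632 (standard parents), 334 (standard reciprocal), 359 (hybrids), 2857 (CNS parents), 583 (CNS reciprocal), 1561 (planned reciprocal interaction), and 1 and 17 (nucleus-matched, reciprocal and parents). In embryo they were 1476 (standard parents), 1701 (CNS parents), 15 (CNS reciprocal), 21 (planned reciprocal interaction), and 2 and 35 (nucleus-matched). Without a filter, which leaves more genes to test, endosperm gave 2786, 675, 694, 3051, 1144, 1972, 51 and 206 in the same order; embryo gave 4 (CNS reciprocal), 11 (planned reciprocal interaction), and 1 and 15 (nucleus-matched).

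With the replicate block endosperm gave 2716, 266, 331, 2849, 499, 1535 and, for nucleus-matched parents, 4. Embryo gave 2428, 2 (standard reciprocal), 2484, 13 (CNS reciprocal), 6 (planned reciprocal interaction), 4544 (planned parents interaction), 3 and 40; parent of origin in CNS embryo gave 22. The block changed no other call of a gene named here. In standard endosperm and CNS embryo, groups share numbers only, and 4 of 4 groups correlated best on average with their own number, a hint from the data. A fit of the compared groups alone, with fewer samples, gave 2649, 114, 277, 389 and 9 in endosperm, and 0 (standard reciprocal), 287 (CNS parents) and 4 (nucleus-matched parents) in embryo. Library totals gave 0 for the standard reciprocal embryo and 3 for nucleus-matched parents in embryo. The opposite alignment gave 0 and 1 for the interactions in endosperm and 7 for parents in embryo. A fold above 2 left 10445 genes between tissues, and the arithmetic mean left 3 and 0 hybrid genes. The gene lists had 2 calls with an estimated correlation, from 106.

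Without the dosage offset, by construction, endosperm gave 5742 and 3916 genes by parent of origin, and genes that were not called turned sign: NRPD1 0.049 and 0.23 in standard and CNS seeds, PHE2 0.92 and 0.97, HDG8 1.00, ALN 0.87 and FH5 0.77 in CNS seeds. The rule on shares gave 166 and 13 in standard endosperm and embryo, 18 in CNS embryo and 3 for the interaction. The dosage slope was 0.41 in endosperm over all genes, 0.49 with library totals and 0.23 above log2 CPM 5; in embryo it was -0.0278 over all genes and 0.34 above 5.

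With each library left out the ranges were, in standard endosperm, 647 to 973 (parents), 3 to 19 (reciprocal), 73 to 148 (hybrids) and 118 to 1143 (parent of origin). In CNS endosperm they were 734 to 2322, 6 to 253, and 100 to 173 (parent of origin). Planned interactions in endosperm ranged from 239 to 919 (reciprocal) and 2572 to 4784 (parents), and nucleus-matched parents from 1 to 41. In standard embryo they were 425 to 527, 0 to 1, 57 to 74 and 38 to 84, and in CNS embryo 507 to 711 and 1 to 514 (parent of origin). In embryo planned parents ranged from 1364 to 2086 and nucleus-matched parents from 3 to 7; the dosage slope ranged from 0.53 to 0.73 and, in embryo, 0.0827 to 0.18. Tissues kept 15655 to 16007 and 14193 to 14656. RBCS2B between CNS parents ranged from -2.32 to 6.65 log2, reversed without Col(C24) replicate 2. For the log2 ratio of HDG8, parent of origin standard endosperm, the range was -0.13 to 0.30, and for HDG8, parent of origin CNS endosperm, -0.10 to 0.0549. For ALN, parent of origin standard endosperm, it was -0.00685 to 0.30. For FH5 it was -0.15 to 0.32 in standard and -1.10 to 0.56 in CNS seeds, and for MPC -1.77 to 2.66 in CNS seeds.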

Other observations

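The tests in this part were chosen after the data were seen. Some differences between Col and C24 were shared by both tissues. SADHU1-1 and SADHU3-2, retroelements of plants that accessions silence in different ways, the albumin gene SESA1, the antenna gene LHCB1.2 and SC35 differed in the same direction in endosperm and embryo. Of the genes called between selfed Col and C24 in both tissues, 168 were higher and 129 lower in Col in both, and 4 had opposite directions, where 33.4 would be shared by chance. Between the CNS lines 160 and 170 were shared and 6 had opposite directions (34.6 by chance).

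Heat stress genes such as HSFA2 and the small heat shock genes varied together in endosperm and embryo of the same cross and replicate number, a relation looked for after the data were seen. Levels in this part are the mean log2 CPM of the members of a list, with 0.5 CPM added. Over 16 pairs these levels had r = 0.967 (permutation p = 1e-05, the smallest possible, and adjusted p = 8.5e-05 over 17 lists) and rho = 0.944 (permutation, adjusted p = 0.00017). Without the 2 farthest pairs r was 0.969, and it was 0.978 within standard and 0.967 within CNS seeds (8 pairs each). Mitochondria-encoded genes (r = 0.871), seed coat markers (0.775), storage genes (0.769), type I MADS (0.744), paternally expressed imprinted genes (0.741), endosperm markers (0.73) and maternally expressed imprinted genes (0.605) had smaller values. Within standard and CNS seeds they were 0.494 and 0.885, 0.740 and 0.568, 0.871 and 0.805, 0.902 and 0.653, 0.849 and 0.719, 0.949 and 0.662, and 0.761 and 0.694. Without their 2 farthest pairs these were 0.777, 0.729, 0.751, 0.771, 0.747, 0.652 and 0.377, and for the maternally expressed genes rho had adjusted p = 0.058 (permutation). The other 9 lists ran from r = -0.436 (mitochondrial dysfunction genes, rho = -0.524, permutation adjusted p = 0.076; -0.781 without the 2 farthest pairs, -0.755 in standard and -0.143 in CNS seeds) to 0.438 (chromatin silencing genes; -0.0628 without the 2 farthest pairs). Auxin synthesis genes had r = 0.165, with 0.809 in standard and -0.125 in CNS seeds.

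Seed coat markers summed to 798 ± 257 CPM in standard endosperm and 452 ± 209 in CNS endosperm (n = 8 libraries each). The median maternal share was 69.6% with a Col mother and 65.4% with a C24 mother in standard endosperm, 69.9% and 64.3% by nucleus in CNS endosperm, 53.2% and 49.2% in standard embryo, and 53.4% and 48.4% in CNS embryo. The tissue comparison with cross and replicate number as a block, added after the data were seen, called 16060 genes in the standard crosses (15704 shared with the unblocked test) and 14276 in CNS crosses (13880 shared).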
